A study of Tachysurus vachellii with 12 samples.

How the data were processed

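Liver mRNA and small RNA of juvenile Tachysurus vachellii were measured in 3 control pools (6.8 mg/L oxygen) and 3 hypoxia pools (0.7 mg/L for 4 h), each of 5 livers. Per the labels, the authors trimmed the mRNA reads, assembled them with Trinity and estimated reads per assembled gene; the submitters' processing notes name RSEM 1.2.3 and DESeq for mRNA and Bowtie for small RNA. The deposited mRNA table holds estimated counts (expected counts) for each of 34744 assembled genes in 6 libraries, not scaled and with fractions, together with an effective length in bases (other unit) and the authors' FDR (a p-value), whose values equal those of the p-value column in all 34744 components. The deposited small RNA table holds raw expected counts per mature sequence, with fractions, as would follow if reads matching several sequences were split, and the p-value of the authors' test. It also holds signal values that the authors made by normalizing, which are the raw counts times 1 constant per library (0.8781 to 1.4156, checked on the values). No genome coordinates are given for the assembled genes, and the reference supplied for gene names was not used for positions. Libraries were assigned by the group codes and letters in the column names and sample titles, and no column was left unassigned.

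Small RNA counts were taken once per mature sequence (545 of 613 entries), and sequences with identical values in all libraries once (471). Rounded counts were tested in edgeR 4.0.16 with the quasi-likelihood test, TMM normalization and filterByExpr, hypoxia against control, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Counts per 1000000 (CPM) use TMM-scaled library sizes, and the log values for set tests use a prior count of 2. Standard errors (SE) of the log2 fold change were derived from the edgeR test. Each is the absolute log2 fold change divided by the square root of the F statistic. Total counts ranged from 32652402 to 35852327 in mRNA and from 4510770 to 7049919 in small RNA. Replicate pools differed beyond counting noise: the median squared difference per gene between pools of 1 group was 3.2 to 9.31 times the Poisson value in mRNA and 20.4 to 93.1 times in small RNA. These ratios scale libraries by their raw totals and not by TMM, so differences in library composition are part of them. The tests ran in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made in Python 3.11.15 with pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

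Whether the letters pair the samples was checked on deviations from group means. Correlations across genes between the same letters of the 2 groups were 0.15, 0.19 and 0.31 for a, b and c in mRNA and 0.13, 0.5 and 0.56 in small RNA, where genes are not independent replicates, and pairs of different letters gave -0.29 to 0.18 and -0.6 to 0.42. Per the labels both groups came from the same 3 aquaria, but no label says that a letter marks an aquarium, so the letter was used as a replicate block in an alternative.

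Gene groups were 23 mRNA lists and 10 miRNA lists, written from textbook knowledge before the data were examined and matched by symbol or protein name, with the most abundant component standing for a gene. The mRNA lists were HIF target genes and HIF pathway; glycolysis and lactate; gluconeogenesis and glycogen; pyruvate dehydrogenase and TCA cycle; oxidative phosphorylation; fatty acid oxidation, lipid and cholesterol synthesis, heat shock and unfolded protein response, antioxidant and glutathione, apoptosis and cell cycle arrest, cell proliferation, ribosome biogenesis, immediate early genes, circadian clock, acute phase with complement and inflammation, amino acid catabolism and nitrogen, bile acid and xenobiotic metabolism, hepatocyte secreted proteins, and markers of erythroid cells, exocrine pancreas, leukocytes and macrophages, muscle, and endothelium with stellate and bile duct cells. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. KEGG pathways named in the deposited table (112 with at least 15 tested genes) were tested the same way after the data were seen.

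Genes chosen for naming are, by a fixed rule, the 8 highest and the 8 lowest fold changes among named genes that passed, were separated between groups and reached a group mean of 10 CPM; the 2 members of each list with the smallest adjusted p; and hif1a, epas1, egln3, vegfa, epo, igfbp1, ldha, hba, hbb and prss1 in all cases. Other list members that passed, the members of 6 KEGG pathways that passed, vegfaa, the members of hypothesis lists that passed, and a few members given as values without a call (such as gapdh) were chosen after their values were seen. Some of the genes chosen for naming are not reported here, and they stay in the counts of genes chosen. For miRNAs the rule takes those past the threshold and miR-210, miR-122, miR-462, miR-731, miR-21, miR-451, miR-144 and let-7a, the most abundant sequence of each family.

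Alternatives were DESeq2, limma-voom, RLE size factors, library size only, no low-count filter, a filter of 5 CPM in 3 libraries, the replicate block, a minimum absolute log2 fold change of 1, an adjusted p of 0.1, each library left out in turn, all matching components per list gene, and, added later, both letter c libraries left out. The pipeline was tested on simulated data of the same size over 5 draws: edgeR recovered 8.8% of 2-fold and 67.8% of 4-fold mRNA changes with 13.9% false calls, and 20% and 76% in small RNA with 6.7% false calls, and camera and fry found the changed list in 100% of draws. Each draw changed 100 mRNA genes and 20 small RNA sequences at each fold, and edgeR called 89 and 20.6 on average. The data gave 1617 and 1 calls. Recovery at an adjusted p depends on the share of genes changed, so these rates may not hold for the data. The simulated genes were drawn independently, and the changed list held only genes made to rise. The draws therefore do not show how the list tests behave where genes of a list are correlated. Left out were 181 gene ontology cells whose text had been removed and 1 emptied line. Targets of the miRNAs in this fish were not analysed here, and only a list of genes known as miR-210 targets in mammals was tested.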

Results

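Liver was profiled in juvenile Tachysurus vachellii, a bagrid catfish that the series title calls Pelteobagrus vachelli, at normal oxygen (control, 6.8 mg/L) and after 4 h of hypoxia (0.7 mg/L). Each library came from a pool of 5 livers, with 3 pools per group lettered a, b and c. Both groups were sequenced as mRNA and as small RNA, giving 12 libraries in all. The mRNA libraries held 32876849, 34104589 and 34224292 counts in control a, b and c. They held 33165652, 35852327 and 32652402 counts in hypoxia a, b and c. The small RNA libraries held 4510770, 7049919 and 4664705 counts in control a, b and c. They held 6976511, 6575783 and 6474476 counts in hypoxia a, b and c. At these depths 3 counts correspond to 0.084 to 0.092 counts per 1000000 (CPM) in mRNA and to 0.426 to 0.665 CPM in small RNA, which covers counting error only.

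The mRNA comparison asks how liver transcripts differ after 4 h at low oxygen. Genes of the hypoxia-inducible factor (HIF) pathway and of glycolysis were among those that rose. EGLN3 (comp17165_c0), a prolyl hydroxylase that marks HIF alpha subunits for degradation, rose from 4.96 ± 2.16 to 133 ± 0.427 CPM (mean ± SD, n = 3, log2 fold change 4.74, SE 0.32, adjusted p = 0.00012). Erythropoietin (epo, comp7521_c0), the hormone that drives red cell formation, rose from 4.05 ± 1.05 to 44.7 ± 8.66 CPM. The gene ldha (comp5908_c0), whose enzyme makes lactate from pyruvate, rose from 8.14 ± 1.11 to 55.3 ± 3.46 CPM. Nr1d1 (comp16984_c0), a repressor in the circadian clock, fell from 30.3 ± 10.3 to 5.44 ± 2.73 CPM. LPL (comp19104_c0), the lipase that releases fatty acids from circulating lipoproteins, fell from 102 ± 15.9 to 27.6 ± 3.7 CPM. The message of the HIF-1 alpha subunit itself, hif1a (comp16248_c0), stood at 60.1 ± 1.5 and 73.2 ± 14.4 CPM and did not pass the test (log2 fold change 0.28, adjusted p = 0.41). Of 25415 genes tested, 1159 rose and 458 fell, and 812 of these 1617 carry a gene name. In 1616 of the 1617 the 3 hypoxia libraries all lay on the same side of the 3 controls, which follows largely from selecting genes by the test. In the same way 7191 of all genes tested (28.3%) were separated, where chance gives 10% on average. Genes are not independent, so a single split can lie far from that average, and the share is not a test.

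The counts moved with the libraries used: 338 rose and 45 fell without control a, 430 and 88 without control b, 596 and 106 without hypoxia a, and 607 and 99 without hypoxia b. Without control c 1040 rose and 515 fell, and without hypoxia c 1337 and 518, and 349 of the 1617 genes passed in each of these 6 fits. With the letter as a replicate block 1695 rose and 798 fell, and 1601 of the 1617 passed in the same direction. The libraries control c and hypoxia c stood apart from the other 4 on the second principal component of the mRNA values (-62.28 and -60.96 against 14.28 to 46.25). Without both of them 2337 genes rose and 1479 fell.

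**Figure D1:**
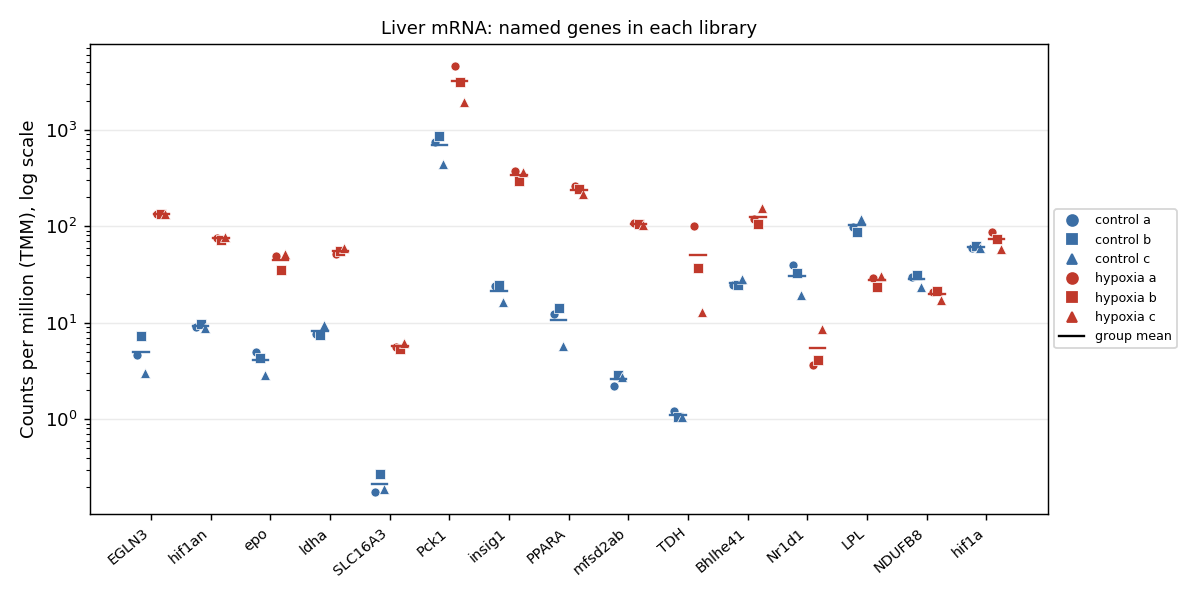
CPM (log scale) of 15 named genes in each mRNA library; symbols mark the letters a, b and c, colours the groups, and lines the group means. EGLN3 sits at 132 to 133 CPM in the 3 hypoxia libraries and at 2.99 to 7.27 CPM in the 3 controls, while hif1a overlaps between the groups.

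Among named genes that reached 10 CPM, the largest rises were those of Ppm1k and TDH. Ppm1k, the phosphatase that activates branched-chain keto acid breakdown in mitochondria, rose from 3.39 ± 0.571 to 222 ± 131 CPM (log2 fold change 6.03, SE 0.51, adjusted p = 0.00034). TDH, threonine dehydrogenase, rose from 1.11 ± 0.0785 to 50.1 ± 45.3 CPM (log2 fold change 5.5, adjusted p = 0.0032), with 101, 36.9 and 12.9 CPM in hypoxia a, b and c. SLC43A2, a carrier of neutral amino acids whose annotation names member 1 of its family, rose by 4.85 on the log2 scale (0.724 ± 0.0671 to 21 ± 16.3 CPM). mfsd2ab, named for a lysophospholipid transporter but annotated as FK506-binding protein 1, rose from 2.58 ± 0.349 CPM to between 103 and 107 CPM (log2 fold change 5.34, adjusted p = 1.3e-05). PPARA, a nuclear receptor that switches on fatty acid oxidation genes, rose from 10.7 ± 4.42 to 239 ± 21.3 CPM (log2 fold change 4.49, adjusted p = 0.00022). The peptide hormone gene ADM2 and the mitochondrial carrier slc25a34 rose by 4.38 and 4.33 (adjusted p = 0.0059 and 0.00022). ADM2 had 0.35, 0.273 and 1.84 CPM in control a, b and c. Over all alternatives the log2 fold change of ADM2 ran from 3.96 to 5.92, that of TDH from 4.47 to 5.94 and that of SLC43A2 from 4.08 to 5.28.

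Among named genes that reached 10 CPM and were separated between the groups, the 8 with the largest falls were Nr1d1 (log2 fold change -2.48, SE 0.38, adjusted p = 0.0069), the heparan sulfate sulfotransferase hs6st1b (-2.03), the vesicle trafficking GTPase Rab33b (-1.98), LPL (-1.88), the transcription factors Klf11 (-1.74, annotated as krueppel-like factor 10/11) and grhl1 (-1.74), the glucuronosyltransferase Ugt2a2 (-1.69) and magi3 (-1.68). Their adjusted p ran from 0.0011 for LPL to 0.037 for magi3. Of the 16 genes with the largest rises and falls within these limits, Rab33b, grhl1 and magi3 lost the call when a library was left out, magi3 also in limma-voom, and over all alternatives their log2 fold changes stayed at or below -1.64, -1.47 and -1.35. The other 13 passed under every alternative run. Among all 91 genes chosen for naming that passed, 36 passed under every alternative that tested them and none changed direction. Beside the 13, these were hif1an, P4HA1, EGLN2, BNIP3L, Ca9, ndrg1, Higd1a, epo, SLC2A1, HK1, Pfkl, aldocb, PGAM1, ldha, SLC16A3, GYS1, insig1, fads2, BTG1, Fosl2, Bhlhe41, Nupr1 and Sgms1. The other 55 lost the call under at least 1 alternative. Leaving out 1 library ended the call of 53 of the 91 without control a, 46 without control b, 16 without control c, 40 without hypoxia a, 40 without hypoxia b and 5 without hypoxia c.

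HIF pathway genes rose as a group. Of 27 tested, 14 rose, none fell and 13 did not pass (16 rose and 1 fell adjusted over the list alone). Their median log2 fold change was 1.34, and the set test camera, which compares a list with all other genes, gave adjusted p = 3.7e-12, and adjusted p = 0.19 with an estimated correlation. Some restraints on HIF were among them: hif1an, the asparaginyl hydroxylase of HIF, here annotated as aspartate beta-hydroxylase, rose from 9.18 ± 0.458 to 75 ± 2.82 CPM (log2 fold change 3.03). EGLN2 rose by 2.96 and Vhl by 1.38, while the prolyl hydroxylase EGLN1 did not pass (0.29, adjusted p = 0.49). P4HA1, a collagen prolyl hydroxylase, rose by 3.82 (adjusted p = 7.3e-05), ndrg1 by 3.66 and Higd1a by 2.94. Rises were smaller for TFRC, the transferrin receptor (1.45), Ca9, a carbonic anhydrase (1.67), BNIP3L (1.34), ddit4 (1.7) and PFKFB3 (1.62). A component annotated as VEGF A/B with no gene name (comp17707_c0) rose by 0.96 (adjusted p = 0.0092), and the component named vegfaa (comp14709_c0) rose by 0.94 (adjusted p = 0.025). Epas1, the HIF-2 alpha gene, annotated as hypoxia-inducible factor 1 alpha, had 284 ± 14.4 and 393 ± 59.2 CPM (log2 fold change 0.47, adjusted p = 0.16). Igfbp1, annotated as binding protein 3, had a log2 fold change of 0.25 (adjusted p = 0.77).

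The listed genes of glycolysis, from glucose entry to lactate export, were higher as a group. Of 20 tested, 9 rose, none fell and 11 did not pass (9 rose and 1 fell adjusted over the list alone). Camera gave adjusted p = 3.6e-07, and adjusted p = 0.19 with an estimated correlation. The glucose transporter SLC2A1 rose by 2 on the log2 scale, the hexokinases HK1 and HK2 by 1.78 and 1.26, and Pfkl by 1.52. HK2 lost its call in limma-voom and when any library but hypoxia a was left out. Further along the pathway aldocb rose by 3.11, PGAM1 by 1.7, ldha by 2.77 and the lactate exporter SLC16A3 by 4.73 (0.212 ± 0.0533 to 5.69 ± 0.427 CPM, adjusted p = 6.1e-05). The gene gapdh had a log2 fold change of -0.09 (adjusted p = 0.78). In the KEGG pathway of glycolysis and gluconeogenesis, tested after the data were seen, 6 of 29 genes rose and 3 fell. Its median was -0.05 and its camera adjusted p 0.47, so that wider set was not higher as a group. Among 17 genes of gluconeogenesis and glycogen, 3 rose, 1 fell and 13 did not pass (4 rose and 1 fell adjusted over the list alone). The camera adjusted p of that list was 0.38, or 0.0064 with all matching components in place of the most abundant. Pck1, which commits carbon to glucose, rose from 685 ± 218 to 3220 ± 1340 CPM (log2 fold change 2.24, adjusted p = 0.0083). The glycogen synthase GYS1 rose by 1.36 and the coactivator PPARGC1A by 2.38 (adjusted p = 0.046, lost in limma-voom, with no filter and in 5 of the 6 fits that left out a library), while G6PC, which releases free glucose, fell from 2690 to 1110 CPM (log2 fold change -1.28, adjusted p = 0.015).

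Genes of the respiratory chain lay lower as a group without any passing alone. All 23 oxidative phosphorylation genes had negative log2 fold changes, between -0.5 and -0.1 with a median of -0.34, and 0 of the 23 passed. For this list camera's adjusted p was 0.00095, and adjusted p = 0.9 with an estimated correlation. NDUFB8, a complex I subunit, had 28.1 ± 4.21 and 19.8 ± 2.19 CPM (log2 fold change -0.5, adjusted p = 0.13), and NDUFS8 had -0.45 (adjusted p = 0.14). None of 20 pyruvate dehydrogenase and TCA cycle genes passed (median -0.11, camera adjusted p = 0.39), with SUCLG1 at -0.32 and Pdhb at -0.33. Among 19 fatty acid oxidation genes PPARA rose, the isomerase ECI2, annotated as a multifunctional enzyme of the pathway, fell (log2 fold change -0.92, adjusted p = 0.033) and 17 did not pass (1 rose and 2 fell adjusted over the list alone). The median of that list was -0.12 and its mean 0.06, and camera put it lower at adjusted p = 0.37.

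The listed genes of lipid and cholesterol synthesis were higher as a group by camera. Of 23 tested, 5 rose, none fell and 18 did not pass (7 rose and 2 fell adjusted over the list alone). The list test gave adjusted p = 0.027, and adjusted p = 0.63 with an estimated correlation. Related KEGG pathways, tested after the data were seen, were not higher as groups. In steroid biosynthesis 1 of 18 genes rose (median 0.15, camera adjusted p = 0.71). In biosynthesis of unsaturated fatty acids 2 of 16 rose (median 0.05, camera adjusted p = 0.74). insig1, which retains the sterol sensor in the endoplasmic reticulum, rose from 21.5 ± 4.53 to 341 ± 43 CPM (log2 fold change 3.99, adjusted p = 6.1e-05). The desaturase fads2 rose by 1.53, srebf2 by 0.97 and the sterol enzyme msmo1 by 1.42. The list call ended without control c (adjusted p = 0.13), without hypoxia b (0.068) and with all matching components (0.053). Of 20 genes of amino acid catabolism and nitrogen, 3 rose, 1 fell and 16 did not pass (7 rose and 1 fell adjusted over the list alone). Camera's adjusted p was 0.029, and adjusted p = 0.9 with an estimated correlation. Prodh, which starts proline breakdown, rose by 3.04 (6.98 ± 1.24 to 57.6 ± 46.8 CPM), ARG2 by 1.8 and ass1 by 1.92 (adjusted p = 0.048, or 0.059 with the replicate block). Prodh, ARG2 and ass1 each lost the call in 4 of the 6 fits that left out a library. Prodh and ass1 also lost it in limma-voom, with log2 fold changes of 2.23 to 3.61 and 1.48 to 2.8 over all alternatives. The call of ass1 ended with both other filters too. Odc1, the first enzyme of polyamine synthesis, fell (log2 fold change -0.86, adjusted p = 0.026). The list call, but not that of Odc1, ended without control c (adjusted p = 0.32). The list call also ended without hypoxia a (0.31) or hypoxia b (0.068) and with all matching components (0.065), and Odc1 lost its call without control a, control b, hypoxia a or hypoxia b.

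Stress and growth genes moved in several directions. Of 16 apoptosis and cell cycle arrest genes, 5 rose, none fell and 11 did not pass (7 rose and 1 fell adjusted over the list alone). As a list they gave adjusted p = 0.018, and adjusted p = 0.46 with an estimated correlation. The antiproliferative gene BTG1 rose by 3.16 (21.6 ± 5.37 to 193 ± 44.1 CPM), the cyclin-dependent kinase inhibitor CDKN1B by 1.16, foxo1b by 1.17, the p53 antagonist mdm2 by 0.78 and the survival factor MCL1 by 0.71. BTG1 kept its call under every alternative. CDKN1B, foxo1b, mdm2 and MCL1 each lost the call without control a, without control b and without hypoxia a. The list call ended without control c (adjusted p = 0.078). Of 5 cell proliferation genes, pcna, the sliding clamp of DNA replication, fell (11.5 ± 1.53 to 6.7 ± 0.0836 CPM, log2 fold change -0.77, adjusted p = 0.03) and 4 did not pass, with 3 falling adjusted over the list alone. Camera placed this list lower at adjusted p = 0.021, and adjusted p = 0.38 with an estimated correlation, and the call ended without hypoxia b (adjusted p = 0.059). The replication helicase gene mcm7-b had a log2 fold change of -0.75 (adjusted p = 0.06, or 0.04 with the replicate block). Of 15 immediate early genes, 3 rose, none fell and 12 did not pass (6 rose and none fell adjusted over the list alone). Their list test gave adjusted p = 0.0012, and adjusted p = 0.63 with an estimated correlation. These were nr4a1 (log2 fold change 4.73, 0.228 ± 0.157 to 6.23 ± 4.68 CPM), Fosl2 (1.87) and Atf3 (1.53). In limma-voom nr4a1 and Atf3 lost their calls, as did nr4a1 without control b and Atf3 in 5 of the 6 fits that left out a library. Over all alternatives the log2 fold change of nr4a1 ran from 4.03 to 5.44. Ribosome biogenesis genes gave 0 of 19 past the test, with a median of -0.1. Camera's adjusted p for them was 0.15, or 0.046 with the replicate block, 0.032 with all matching components, 0.016 without control c and 0.00028 without hypoxia a. With an estimated correlation it was 0.93, and 0.84 with the block. Members were RRP9 at -0.74 (adjusted p = 0.16, or 0.045 with the block, and annotated as TUP1) and Nolc1 at -0.54 (annotated as a leukemia protein).

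Few chaperone, antioxidant and inflammation genes passed. Of 26 heat shock and unfolded protein response genes, HSP90AA1 (log2 fold change 1.33, adjusted p = 0.015, annotated as HtpG) and the pseudokinase TRIB3 (1.7, adjusted p = 0.016) rose, and 24 did not pass. Adjusted over the list alone 3 rose, and camera gave adjusted p = 0.84 with a median of -0.14. Of 22 antioxidant and glutathione genes, Nfe2l2, the regulator of that program, rose by 0.62 (adjusted p = 0.045) and Gclc, which starts glutathione synthesis, by 0.79 (adjusted p = 0.022), and 20 did not pass. Nfe2l2 lost its call with no filter and in 5 of the 6 fits that left out a library, and Gclc in 4 of the 6. In that list 2 rose adjusted over the list alone, and camera gave adjusted p = 0.38 with a median of -0.18. Of 17 acute phase, complement and inflammation genes, Nfkbia, an inhibitor of NF-kappa B, rose by 1.06 (adjusted p = 0.017) and 16 did not pass (1 rose adjusted over the list alone). The median of that list was -0.02, its mean 0.01, and camera put it higher at adjusted p = 0.91. hpx, the heme scavenger hemopexin, had a log2 fold change of -0.6 (adjusted p = 0.21).

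Clock genes changed in both directions. Of 15 tested, 4 rose, 1 fell and 10 did not pass (5 rose and 3 fell adjusted over the list alone). The repressor Bhlhe41 rose from 25.8 ± 2.18 to 126 ± 25.3 CPM (log2 fold change 2.29, adjusted p = 0.00041), nfil3 by 1.92, CRY2 by 1.44 and CRY1 by 0.75, while Nr1d1 fell. The list median was -0.02 and its mean 0.14, camera put it higher at adjusted p = 0.48, and fry's test for changes in either direction gave adjusted p = 6.7e-05. That fry test also passed for lists such as fatty acid oxidation (adjusted p = 0.00034), and not for others such as ribosome biogenesis (0.56). Such a result is therefore not particular to the clock list. Per the labels the hypoxia fish were taken hours after the control fish, so the hour and the oxygen level differ together, for these and for all other genes and miRNAs compared.

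Bile acid and xenobiotic genes lay lower as a group. None of 14 passed and the median was -0.5. Camera placed the list lower at adjusted p = 0.014, and adjusted p = 0.46 with an estimated correlation, and the call ended without hypoxia c (adjusted p = 0.19). Cyp27a1, a bile acid enzyme, had 208 ± 15 and 119 ± 32.6 CPM (log2 fold change -0.81, adjusted p = 0.07, or 0.03 with the replicate block), and cyp1a1 had -0.67 (adjusted p = 0.1, or 0.032 with the block). None of 21 hepatocyte secreted proteins passed (median -0.07, mean 0.04, camera higher at adjusted p = 0.99, lower with the block). Their apoa1 stood at 1.35 (adjusted p = 0.077, or 0.034 with the block) and F5 at 0.31. By camera 6 of the 23 lists were higher and 3 lower. With an estimated correlation none of the 23 passed (adjusted p from 0.19 to 1, or 0.53 to 0.99 with the replicate block). The rotation test fry, which asks of each list by itself whether its genes move one way, called the HIF, glycolysis, apoptosis and proliferation lists (adjusted p = 0.0008, 0.0008, 0.048 and 0.018). With the replicate block fry kept the HIF and glycolysis lists (0.036 each), lost apoptosis (0.0505) and proliferation (0.051), and called lipid synthesis and bile acid (0.036 each).

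**Figure D2:**
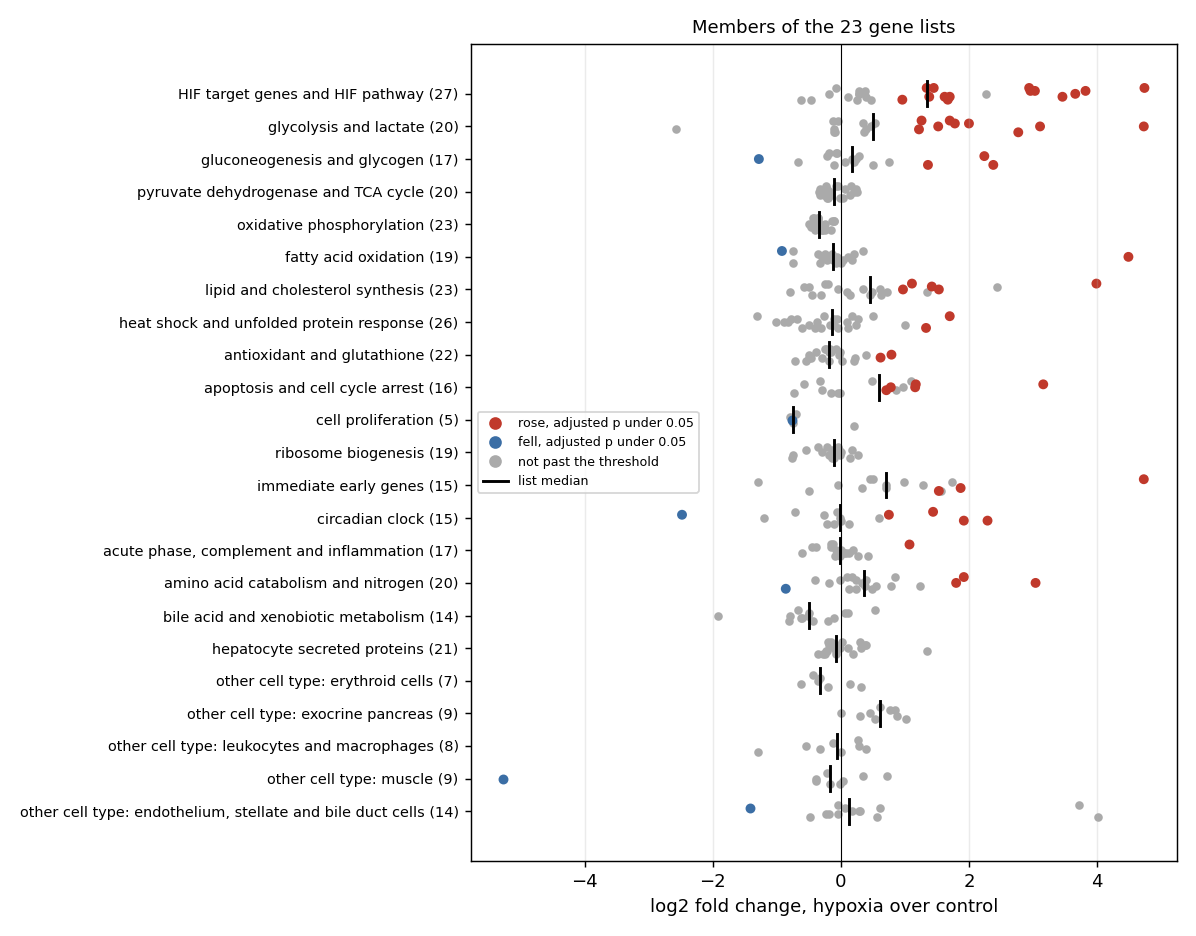
Log2 fold change (hypoxia over control) of each tested member of the 23 gene lists, with the number tested in parentheses; red and blue points passed the test, grey points did not, and black lines are list medians. The HIF list has its median at 1.34, and all 23 oxidative phosphorylation genes sit left of 0.

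Among markers of other cell types CKM and HAND2 passed, and pancreas and globin genes differed widely between pools. All 9 exocrine pancreas genes had positive log2 fold changes and none passed (median 0.61, camera adjusted p = 0.1, or 0.0053 with the replicate block and 0.00059 without control a). With an estimated correlation their adjusted p was 0.9, and 0.74 with the block. The pancreatic lipase CEL had 1070, 317 and 7.51 CPM in control a, b and c and 1900, 525 and 401 CPM in hypoxia a, b and c. Trypsin (Prss1) had 287, 82.2 and 3.33 against 415, 138 and 121 CPM, and clps had a log2 fold change of 0.46 (adjusted p = 0.69). CEL stood at 1.01 (SE 1.18, adjusted p = 0.67), or at -0.02 without hypoxia a. None of 7 erythroid genes passed (median -0.32, camera adjusted p = 0.39, or 0.047 without hypoxia c and 0.00057 without both letter c libraries, but 0.93 with an estimated correlation), with epor at -0.63 and RHAG at -0.43. Alpha globin (hba) had 924, 1280 and 688 CPM in the controls and 280, 752 and 1240 CPM in hypoxia a, b and c. The beta globin hbb had a log2 fold change of -0.32 (adjusted p = 0.74), and both globins turned positive without hypoxia a, at 0.04 and 0.06. None of 8 leukocyte and macrophage genes passed (median -0.06, camera adjusted p = 0.76), with MMP9 at -1.29 (adjusted p = 0.083, or 0.018 with the block) and ITGB2 at -0.54. Of 9 muscle genes CKM fell (log2 fold change -5.27, adjusted p = 0.042), from 23.6, 0.182 and 18.1 to 0.242, 0.304 and 0.531 CPM, with control b at the hypoxia level. It lost its call in limma-voom (log2 fold change -3.63) and when any library but control b was left out. Desmin (des) did not pass (0.72, or adjusted p = 0.041 with the block). Of the muscle genes 1 rose and 1 fell adjusted over the list alone, and camera gave adjusted p = 0.84, or 0.038 without control b. Of 14 endothelium, stellate and bile duct genes HAND2 fell (-1.42, adjusted p = 0.026), also adjusted over the list alone, and 13 did not pass (median 0.12, camera adjusted p = 0.84), with ACTA2, annotated as gamma-enteric actin, at 0.56.

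In the table deposited by the authors, 961 genes were marked as changed, 712 higher and 249 lower in hypoxia. Of these, 939 were tested here, and 869 also passed here, all 869 in the same direction. Another 748 genes that passed here were not marked there. The smallest absolute log2 fold change among the marked genes was 1, and no such minimum was applied here. That minimum cannot by itself account for the 748, because only 1049 deposited components had an FDR under 0.05. With a minimum of 1 applied here, 982 genes rose and 299 fell. Other causes of the difference were not tested.

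In small RNA the comparison asks which liver miRNAs differ after the same hypoxia. miR-210-5p, an arm of miR-210, which is known for its induction by HIF in mammals, rose from 78.3 ± 20 to 378 ± 87.3 CPM (n = 3; log2 fold change 2.27, SE 0.32, adjusted p = 0.025) and was higher in 3 of 3 hypoxia pools. Its partner arm miR-210-3p had 104 ± 10.8 and 210 ± 82.2 CPM and did not pass (log2 fold change 1.01, adjusted p = 0.45, or 1.38 and 0.045 without both letter c libraries). miR-122-5p, the dominant liver miRNA, took 42.67% to 54.33% of each library and had a log2 fold change of 0.11 (adjusted p = 0.88). Of 238 mature sequences tested by edgeR, 1 rose and 0 fell, where 22 had an unadjusted p under 0.05, and DESeq2 and limma-voom also gave 1 and 0. The call of miR-210-5p ended without control a (adjusted p = 0.16), control b (0.2), hypoxia a (0.1) or hypoxia b (0.18). It also ended with library size as the only scaling (0.053), which moves the median log2 fold change of all miRNAs from 0.021 to -0.188.

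Other miRNAs fixed for reporting did not pass. The fish miRNAs miR-462 and miR-731 had log2 fold changes of 0.06 and -0.36 (adjusted p = 0.94 and 0.78), miR-21 had -0.07, the erythroid miRNAs miR-451 and miR-144 had -0.44 and -0.48 (0.08 and 0.37 without control a), and let-7a had 0.37. With library size as the only scaling miR-122-5p and miR-462 turned to -0.04 and -0.07. With the letter as a replicate block 1 miRNA rose and 2 fell, and without both letter c libraries 5 rose and 6 fell. Control c and hypoxia c stood apart on the first principal component of the miRNA values (-9.15 and -5.29 against -0.1 to 7.81 in the other 4). The falls with the block, chosen for naming after their values were seen, were miR-19b-3p (log2 fold change -1.17, adjusted p = 0.66, or 0.029 with the block) and miR-19a-3p (-1.41, adjusted p = 0.69, or 0.029 with the block). miR-19b-3p had 780, 821 and 3490 CPM in control a, b and c and 340, 335 and 1590 CPM in hypoxia a, b and c, so it was lower in 3 of 3 letters and highest in the letter c library of each group. Its log2 fold change went to -0.18 without control c and to -2.32 without hypoxia c. That of miR-19a-3p turned to 0.28 without control c and went to -3.19 without hypoxia c.

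None of the 10 miRNA lists passed camera. With an estimated correlation each had adjusted p = 0.41, or 0.54 with the replicate block. Among 30 hypoxia-associated miRNAs miR-210-5p rose and 29 did not pass (1 rose adjusted over the list alone; median 0.09, camera adjusted p = 0.099, or 0.029 without control c). The other 9 lists had no member past the test, over all miRNAs or adjusted over the list alone. The 16 members of the miR-17-92 and paralogous clusters had a median of -0.45 (adjusted p = 0.069). For them the p was 0.0096 with the replicate block, 0.034 with library size only, 0.017 without control a, 0.033 without control c and 0.011 without hypoxia a. Medians were -0.44 for 7 erythroid miRNAs (adjusted p = 0.099, or 0.0095 without control c), -0.46 for 5 muscle miRNAs (0.14, or 0.044 without control b) and -0.26 for 8 leukocyte miRNAs (0.16). They were 0.74 for 6 pancreas miRNAs (0.14, or 0.038 with the block) and 0.3 for 7 epithelial and bile duct miRNAs (0.15). The let-7 family of 9 had a median of 0.2 (adjusted p = 0.35), 12 endothelial and mesenchymal miRNAs had 0.07 (0.32). The 21 hepatocyte-abundant miRNAs had a median of 0.03 and a mean of -0.12, with camera lower at adjusted p = 0.35.

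**Figure D3:**
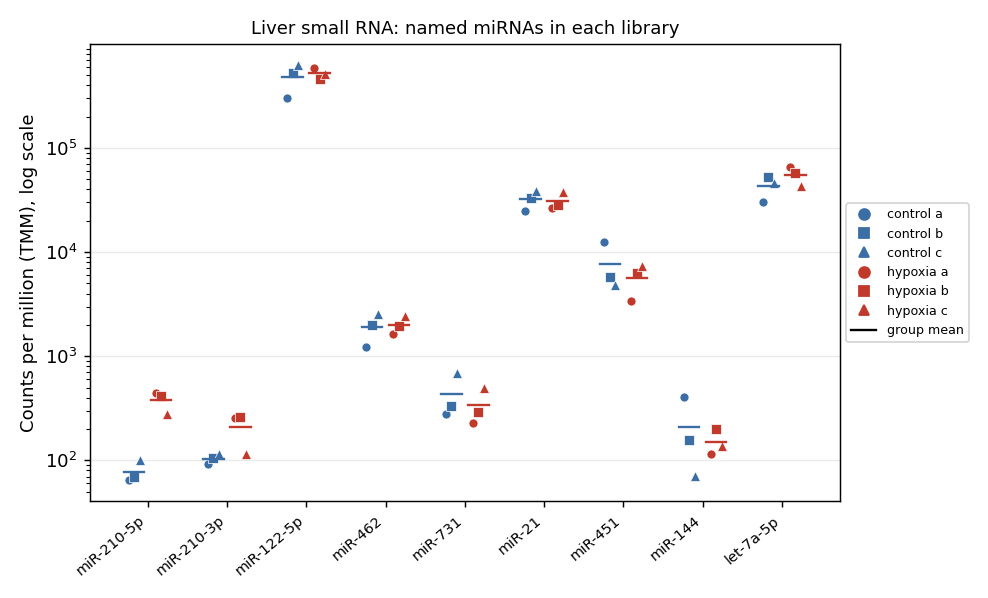
CPM (log scale) of the named miRNAs in each small RNA library; symbols mark the letters a, b and c, colours the groups, and lines the group means. miR-210-5p sits at 278 to 440 CPM in the 3 hypoxia libraries and at 64.5 to 101 CPM in the 3 controls, and the other miRNAs plotted did not pass the test.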

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

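The alternatives chosen after seeing the data are the fits without both letter c libraries, the scaling and left-out-library alternatives of the mRNA lists, and every alternative of the miRNA lists. Of the 1617 mRNA genes past the threshold, 1612 also passed in DESeq2, 1336 in limma-voom, 1600 with RLE factors, 1505 with library size only, 1330 with no filter, 865 with the filter of 5 CPM in 3 libraries (which tested 8893 genes) and 1601 with the replicate block, all in the same direction, and 243 passed in every fit. Of the 91 genes chosen for naming that passed, 36 passed under every alternative and 41 lost the call only when a library was left out. Of the 26 that did not pass, 13 passed under at least 1 alternative. The pseudocount alternatives were not run, because the values are counts. A fit without 1 library tests 3 pools against 2, which lowers its power. Power alone does not account for the counts, because 1855 genes passed without hypoxia c. How far each count falls or rises depends on the library left out, and each other cause was not tested. Depth limits genes near 0.09 CPM.

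With the number of genes that rose or fell standing at 1159 and 458, the filter of 5 CPM in 3 libraries, which tests fewer genes, gave 719 rises. An adjusted p of 0.1, a looser threshold, gave 1824 and 1029, and a minimum absolute log2 fold change of 1 gave 299 falls. DESeq2 gave 797 falls and the replicate block 798 (the cause was not tested). Without both letter c libraries 2337 rose and 1479 fell. Leaving out 1 library gave 338 (without control a) to 1337 (without hypoxia c) rises and 45 to 518 falls, for the same libraries.

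For miRNAs, library size only gave 0 rises, the replicate block 2 falls, and the fit without both letter c libraries 5 rises and 6 falls. Leaving out 1 library gave 0 (without control a, control b, hypoxia a or hypoxia b) to 1 rise. The log2 fold change of miR-210-5p stayed between 2.09 and 2.69, with adjusted p from 1.8e-07 in DESeq2 to 0.2 without control b.

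Of the mRNA lists, 6 were higher and 3 lower. The estimated correlation gave 0 and 0, fry 3 and 1, and leaving out 1 library 3 (without control c) to 7 (without control a) higher. Directions turned for lists that did not pass. The hepatocyte list turned with the replicate block (adjusted p = 0.99) and with all matching components (0.8), the heat shock list with all matching components (0.81) and without both letter c libraries (0.2), and the clock list with all matching components (0.99). With libraries left out, lists that turned for at least 1 of them had an adjusted p of 0.54 to 0.95 (hepatocyte), 0.44 to 0.81 (heat shock), 0.23 to 0.88 (acute phase) and 0.078 to 0.93 (TCA cycle). The ranges were 0.00028 to 0.82 for ribosome biogenesis, 0.047 to 0.8 for erythroid cells, 0.41 to 0.8 for leukocytes and 0.038 to 0.89 for muscle.

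For the miRNA lists, where none passed, the replicate block called 1 higher and 1 lower (pancreas, adjusted p = 0.038, and miR-17-92, 0.0096), and library size only called 1 lower (miR-17-92, 0.034). With an estimated correlation none was called, with or without the block (adjusted p = 0.54 and 0.41 for each list). Without both letter c libraries 1 was higher (hypoxia-associated, 0.023) and 2 were lower (miR-17-92, 0.023, and erythroid, 0.0022). Leaving out 1 library gave 0 to 1 higher and 0 to 2 lower. The adjusted p then ran from 0.029 to 0.47 for hypoxia-associated, 0.011 to 0.15 for miR-17-92, 0.0095 to 0.62 for erythroid and 0.044 to 0.65 for muscle miRNAs.

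None of the 91 changed direction. Log2 fold changes of other named genes that turned when a library was left out ran from -0.02 to 2.53 (CEL), -0.38 to 0.77 (clps), -0.21 to 0.62 (Igfbp1), -0.92 to 0.04 (hba) and -0.88 to 0.06 (hbb), each turning without hypoxia a. With library size only miR-122-5p had -0.04 and miR-462 -0.07, and with the filter of 5 CPM miR-462 had -0.02. Without 1 library the ranges were -0.14 to 0.26 (miR-122-5p), -0.18 to 0.23 (miR-462), -0.73 to 0.06 (miR-731), -0.24 to 0.01 (miR-21), -0.75 to 0.08 (miR-451), -0.96 to 0.37 (miR-144) -2.32 to -0.18 (miR-19b-3p) and -3.19 to 0.28 (miR-19a-3p).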

Other observations

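The pathway tests, the choice of the clock genes for weighing and the fits without both letter c libraries were made after the results were seen. Of the 112 KEGG pathways named in the gene table, those that camera called lay lower in hypoxia, except sphingolipid metabolism. Genes that copy and repair DNA were among the lower ones. Retinol metabolism (median -0.31, camera adjusted p = 0.0072) and SNARE interactions (median -0.16, adjusted p = 0.033) were lower too. With an estimated correlation these had adjusted p = 0.7 and 0.98. A lower position was therefore not particular to DNA copying and repair. Of 25 DNA replication genes 4 fell (pcna, RPA2, RNASEH2C and a component named PEO1 but annotated as DNA polymerase I), with a median log2 fold change of -0.44 and camera's adjusted p = 1.1e-05, and adjusted p = 0.64 with an estimated correlation. RPA2, which coats single-stranded DNA, had a log2 fold change of -1.31 (adjusted p = 0.017), and PEO1 of -2.11 (adjusted p = 0.014). PEO1 was low in both groups, at 1.1 ± 0.313 CPM in control and 0.252 ± 0.0392 CPM in hypoxia. Of 38 nucleotide excision repair genes 5 fell, adding ercc3 (-0.8) and MNAT1 (-1.14) to pcna, RPA2 and PEO1 (adjusted p = 6.7e-05, and adjusted p = 0.64 with an estimated correlation). Of 28 base excision repair genes POLL (-1.28), PEO1 and pcna fell (adjusted p = 7.5e-05, and adjusted p = 0.64 with an estimated correlation). Each of these falls was lost in at least 3 of the 6 fits that left out a library.

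Heparan sulfate synthesis genes also lay lower: of 16, hs6st1b (-2.03), HS3ST3B1 (-0.95) and B4GALT7 (-1.08) fell, with camera's adjusted p = 0.006, and adjusted p = 0.67 with an estimated correlation. HS3ST3B1 lost its call in 4 and B4GALT7 in 3 of the 6 fits that left out a library. Sphingolipid genes lay higher: of 25, Sgms1, which makes sphingomyelin, rose from 24.2 to 97.3 CPM (log2 fold change 2.01), and Neu2 (1.27), UGT8 (1.01), SPHK2 (0.94) and degs1 (0.73) rose. Of these Sgms1 kept its call in all 6 such fits, while Neu2 lost it in 2, UGT8 in 3, SPHK2 in 5 and degs1 in 4. Camera's adjusted p for that pathway was 0.012, and adjusted p = 0.73 with an estimated correlation. The 98 ribosome genes (median -0.2, adjusted p = 9.6e-06) and the 39 proteasome genes (median -0.29, adjusted p = 1.1e-05) were lower as groups, with 0 past the test in either and adjusted p = 0.99 and 0.85 with an estimated correlation.

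All 23 oxidative phosphorylation genes of the fixed list had negative fold changes. A bias with transcript length was tested by removing each library's trend with effective length: the median of the list, here from differences of mean log values in place of the edgeR fit, went from -0.33 to -0.3 (quartiles -0.35 and -0.21), and camera's p from 0.00012 to 0.00043. This argues against length as the whole cause, although p = 0.44 with an estimated correlation after the removal leaves the call as it was, resting on the preset correlation. Ribosome and proteasome genes also lay lower (medians -0.2 and -0.29), while sphingolipid genes lay higher (0.25), so a small fall as a group was not particular to the respiratory chain. A lower expression of the respiratory chain in hypoxia stays open as an untested biological explanation.

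Of the clock genes, 5 passed, with Bhlhe41 higher and Nr1d1 lower. A later hour of sampling may account for these 5, as may hypoxia itself, since Bhlhe41 is also a known HIF target. No untreated fish of the later hour were measured, so the hour and the oxygen level cannot be told apart for these genes. The same holds for every other gene and miRNA that differed between the groups.

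Ppm1k, TDH, SLC43A2 and Prodh, which handle amino acids, rose, and a candidate explanation was a wider amino acid response through the factor ATF4. The 19 other ATF4 target genes listed for this test had a median log2 fold change of 0.07 (quartiles -0.3 and 0.33), below the 0.2 set in advance but by less than their spread. Camera's p for them was 0.6, and fry's p for changes in either direction was 5.3e-06. Only Nupr1 passed among them (log2 fold change 1.6). The list does not hold every stress gene that rose here, such as TRIB3, ddit4 and Atf3, so the test leaves the question open.

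If a rise of miR-210 lowered the messages of its targets, genes known as miR-210 targets in mammals could lie lower. The list does not name the arm that acts on each gene, so it cannot test miR-210-5p by itself. The other arm, miR-210-3p, did not pass (log2 fold change 1.01, adjusted p = 0.45). The 12 tested had a median log2 fold change of 0.12 (quartiles -0.18 and 0.37), with MNT (1.49) and Tcf7l2 (1.07) higher and gpd1l (-0.98) lower. Camera's p for them was 0.58, and fry's p for changes in either direction was 8.9e-05. Whether these genes are targets in this fish was not tested, and the members went both ways, so the test does not settle the question.

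The 6 libraries of each kind can be split 3 against 3 in 10 ways, so a share under 0.1 cannot be reached. For mRNA genes 1 of the 10 splits, the real one, gave as many as 1617 genes, and the highest other gave 0. For miRNAs 1 of the 10 gave as many as 1, and the highest other gave 0. For the mRNA lists 3 of the 10 gave as many as the real 9, the highest other gave 14, and among splits that part all 3 letter pairs the highest other gave 7. For the miRNA lists all 10 gave as many as the real 0, with 3 the highest other. Each other split sets 2 pools of 1 group and 1 of the other against the rest, so part of the group difference stays in it.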
